A study of Mus musculus with 849 samples.

How the data were processed

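Single cells of the dorsal olfactory epithelium were dissociated with papain, sorted, captured on microfluidic C1 chips, and made into cDNA and tagmented libraries, per the labels' protocols. Libraries cover whole transcripts and carry no molecular identifiers, so counts are of reads, PCR copies included, and intervals and floors below cover counting error only. Sequencing was on an Illumina HiSeq, with paired reads in 121 libraries and single reads in 728. Every library has the label of having passed a visual check of its capture chamber, and no doublet caller was run.

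The main table holds whole-number read counts per gene and cell as deposited by the authors. Alternatives used the RSEM expected counts and the kallisto estimated counts, both deposited by the authors as not necessarily whole numbers, which were rounded after summing. The quality table deposited by the authors gives, per the file headers, the fraction of bases in introns, between genes and in mRNA for each cell. The submitters' processing notes name CASAVA, bcl2fastq 2.17, Trimmomatic 0.3.2, TopHat2 2.1.1, featureCounts 1.5.0-p3, Cufflinks 2.2.1, RSEM 1.2.31, kallisto 0.43.0 and the builds GRCm38 and mm10, without roles. Coordinates were taken from a GRCm38 annotation. Of 47083 gene rows of the count table, 5721 were without a value in every cell and were left out, and 2199 rows that share a symbol were summed, which left 39348 symbols. The RSEM table gave 27483 symbols (14549 of 42127 rows without values) and the transcripts of kallisto 26070, with 12.2% of its counts in transcripts matched to no symbol. The 95 control rows (92 spike-ins, reporters and the Cre transgene) stayed out of totals and tests.

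Groups were read from the labels on genotype, time and sort. The replicate is the animal pool of 1 to 3 animals, so p-values measure the spread between pools. Wild type is 1 pool at 72 h and 1 at 96 h, taken as 1 group. Cells with at least 100000 gene counts and 1500 detected genes were kept. Counts were summed over the kept cells of each pool, and all 15 pools entered a single edgeR 4.0.16 quasi-likelihood fit in R 4.3.3 (TMM factors, low-count filter by expression, group as the only term, 8 residual degrees of freedom, common dispersion 1.17) over 19495 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM are counts scaled by library size and TMM factor, and errors are SD over pools for levels and SE for log2 fold changes. A fold against a group without counts is a lower bound from 3 counts over that group. Tests were 2-sided.

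Named genes followed a rule: per contrast the 10 largest rises and 10 largest falls among called genes with mean log2 CPM of at least 4 and pools that do not overlap, passing over predicted and odorant receptor genes, Xist, Tsix and Y-linked genes, up to 4 members of each gene list described, and lineage genes chosen beforehand, among them Trp63, Krt5, Krt14, Sox2, Neurog1, Omp and Cyp2g1. The lists (17 of cell types, 16 of pathways) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a contrast. Some lists share members, so their tests are not independent. The hemidesmosome list shares Col17a1 and Itgb4 with the horizontal basal list. The contrasts, lists, rule, filters and most alternatives were set before the data were examined. With the preset correlation 118 list tests passed, and 12 of these with the estimated one.

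Cells were clustered in Python 3.11.15 on log2(CPM + 1) of the 2000 most variable genes, 30 principal components and 15 neighbours, with Leiden (leidenalg 0.10.2) at resolution 1 and no batch correction. A cluster took the name of the marker list with the most members detected in at least 50% of its cells and at least 2-fold above the other cells (3 or more). Names were decided after the clusters were seen, and clusters with markers of several types, or with markers carried as highly by others, stayed unnamed. Shares carry Wilson 95% intervals. Trends of shares with time used Spearman's and Pearson's correlation over the 11 p63cKO pools with 100000 permutations. Within horizontal-basal-like cells, counts of pools with at least 5 such cells were fitted in the same way.

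On simulated counts of 19495 genes with 200 changed, the 24 h design recovered 1% of genes changed 4-fold and 23% of those changed 16-fold, and the 14 d design 0% and 19%, with 1 unchanged gene called in each. Alternatives were DESeq2 1.42.0, limma on the mean CPM of the cells, median-of-ratios factors, every gene with at least 1 count, chip size or the share of male animals as a covariate, no cell filter or a stricter one (500000 counts and 3000 genes), the other 2 quantifications, the compared groups alone, other clustering settings, and each pool left out in turn. Deposited TPM and FPKM tables were not used here.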

Results

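Single cells of the mouse olfactory epithelium were profiled by RNA-seq. This tissue of the nasal cavity holds the olfactory sensory neurons, the glia-like sustentacular cells around them, microvillous cells, and basal stem cells. Horizontal basal cells, its reserve stem cells, had been marked by a tamoxifen-inducible Cre under the Krt5 promoter that turns on a yellow fluorescent reporter, and the marked cells and their progeny were sorted for fluorescence. They came from wild type animals or from animals in which tamoxifen also deletes Trp63, the gene for the basal epithelial transcription factor p63 (p63cKO). The p63cKO cells were collected 24 h, 48 h, 96 h, 7 d or 14 d after tamoxifen, and the wild type cells at 72 h (replicate 2) or 96 h (replicate 1). A further group was sorted for a Sox2eGFP reporter and against ICAM, F3 and SRB1.

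Of 849 libraries, 680 were of traced cells and 169 of Sox2eGFP cells, and 785 passed the filter of at least 100000 gene counts and 1500 detected genes. The wild type group kept 103 of 107 cells, p63cKO 24 h kept 87 of 98, 48 h kept 99 of 102, 96 h kept 144 of 159, 7 d kept 110 of 111, 14 d kept 100 of 103, and Sox2eGFP kept 142 of 169. The cells came from 15 animal pools, which are the replicates (3 pools at 24 h and 2 in each other group). Kept cells held 103187 to 1886822 counts (median 461218) over a median of 4579 genes. Summed counts per pool ran from 6147139 (p63cKO 24 h replicate 1) to 54950785 (wild type replicate 1). Replicate pools correlated across genes at r = 0.733 to 0.855. The chi-square between their read counts was 192 to 382 per gene. It is set against the counting error of reads alone, and reads include PCR copies, so it does not measure the spread between animals.

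The kept cells formed 15 clusters with the marker genes of several epithelial cell types. Clusters 2 and 7 (95 and 51 cells) carried 6 of 7 horizontal basal markers, among them the basal keratins Krt5 and Krt14, and were called horizontal-basal-like. Clusters 3 and 6 were immature-neuron-like. Cluster 11 was mature-neuron-like with 9 of 9 markers of mature olfactory sensory neurons. Cluster 14 was neuronal-precursor-like, and cluster 8 globose-basal-like, with mitotic genes such as Plk1 and Aspm among its leading genes. Cluster 10 was microvillous-like of the ionocyte type, cluster 13 respiratory-secretory-like, and cluster 15 wound-keratinocyte-like, led by the interleukin 1 antagonist Il1rn and the keratin Krt6a. Clusters 4 and 9 were sustentacular-like, but cluster 4 had none of the sustentacular markers among its top 10 genes and 1 marker of another type, so both are compared by number. Cluster 1 (118 cells) was led by Il6, Tnfaip2, Gstm1 and Irf1, genes of cytokine signaling and detoxification, and cluster 5 (61 cells) by Kit and the replication genes Mcm5 and Mcm6. Both stayed unnamed, as did cluster 12 (25 cells), which carried 7 of 9 mature neuron markers together with sustentacular markers.

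**Figure D1:**
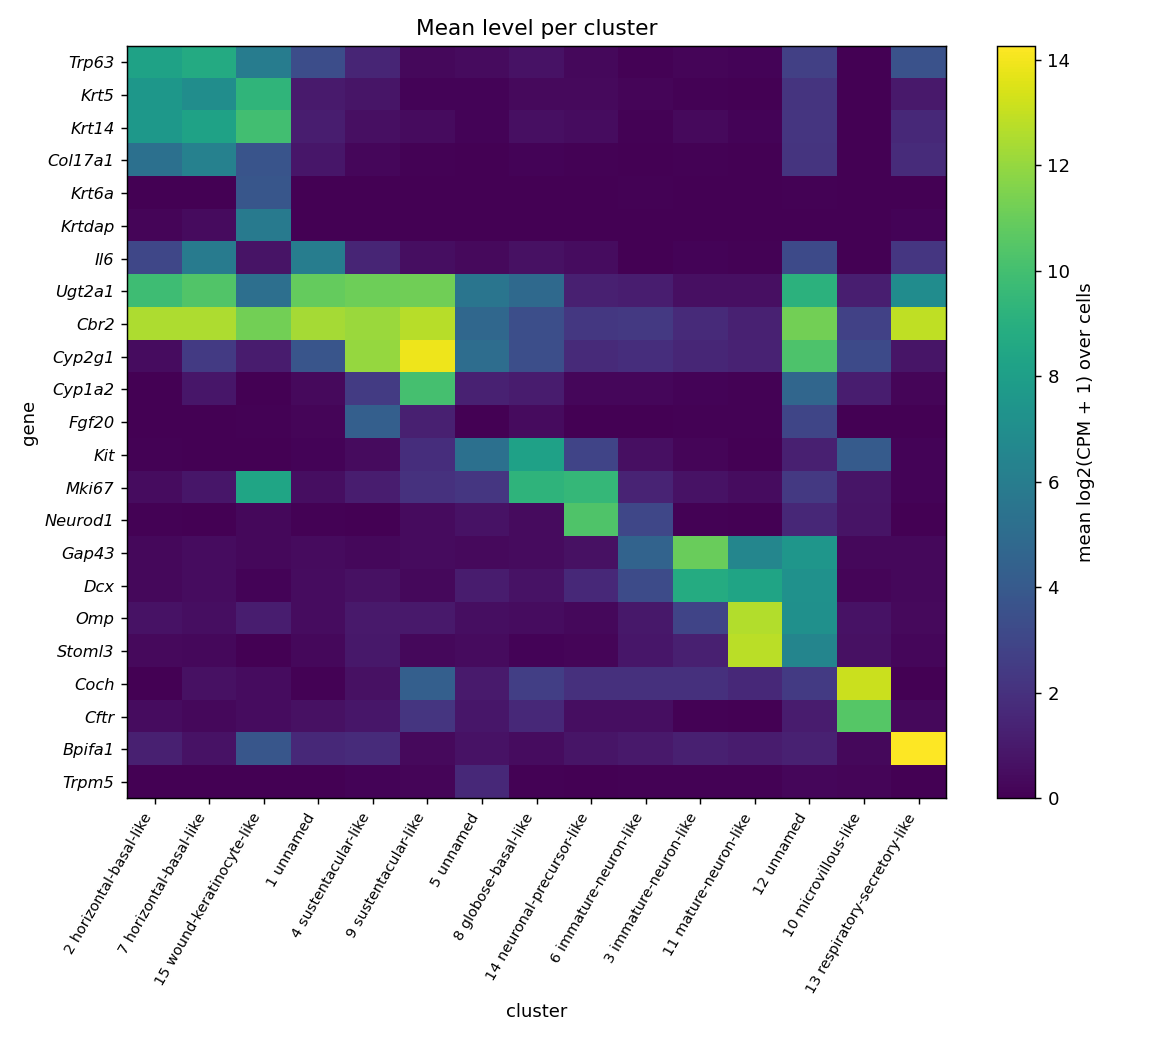
Heatmap of mean log2(CPM + 1) of marker genes (vertical axis) in the 15 clusters (horizontal axis); color gives the mean over the cells of a cluster. The basal keratin genes stand out in clusters 2, 7 and 15 and the mature neuron genes in clusters 11 and 12.

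Trp63 transcripts were lower in the traced p63cKO cells than in wild type at each time. Wild type pools held 1299 and 807 CPM, and the 11 p63cKO pools held 3.82 to 439 CPM. The 24 h group averaged 203 ± 206 CPM (SD, n = 3 pools), 48 h 123 ± 76.1, 96 h 203 ± 42.1, 7 d 26.1 ± 11.8 and 14 d 23.7 ± 28.1 (n = 2 each), against 1053 ± 348 in wild type (n = 2). The mean of the 5 p63cKO groups was 13.3-fold lower, a log2 fold change of -3.73 ± 0.66 (SE; adjusted p = 0.0245, lower in 11 of 11 pools). The share of horizontal-basal-like cells, which carry Trp63, was lower too, with group means of 1.8 to 15.5% against 90.7% in wild type. Within that class single pools were at 1298 CPM at 24 h, 356 at 48 h and 883 at 96 h against a mean of 974 in wild type. With 1 pool at each time, the spread between p63cKO pools is unknown there. Neither Sox2eGFP pool held a Trp63 count, at least 27720-fold below wild type. Trp63 lies on chromosome 16 at 25683763 to 25892102 (plus strand, GRCm38) with 8 annotated transcripts, and a count over the whole gene also takes reads outside the deleted exons, so it is only a partial check of the genotype. No time passed alone: the adjusted p was 0.330 at 24 h, 0.475 at 48 h, 0.656 at 96 h, 0.145 at 7 d and 0.0810 at 14 d. The call for the mean was lost without wild type replicate 1 (-3.34, adjusted p = 0.133), wild type replicate 2 (-4.04, 0.0833), 48 h replicate 2 (-3.63, 0.0568), 96 h replicate 1 (-3.78, 0.0575), 96 h replicate 2 (-3.69, 0.0656) or 7 d replicate 1 (-3.65, 0.0592). It was also lost with the chip covariate (adjusted p = 0.0586), the stricter cell filter (0.279), single reads alone (0.124) and without cluster 12 (0.0574).

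**Figure D2:**
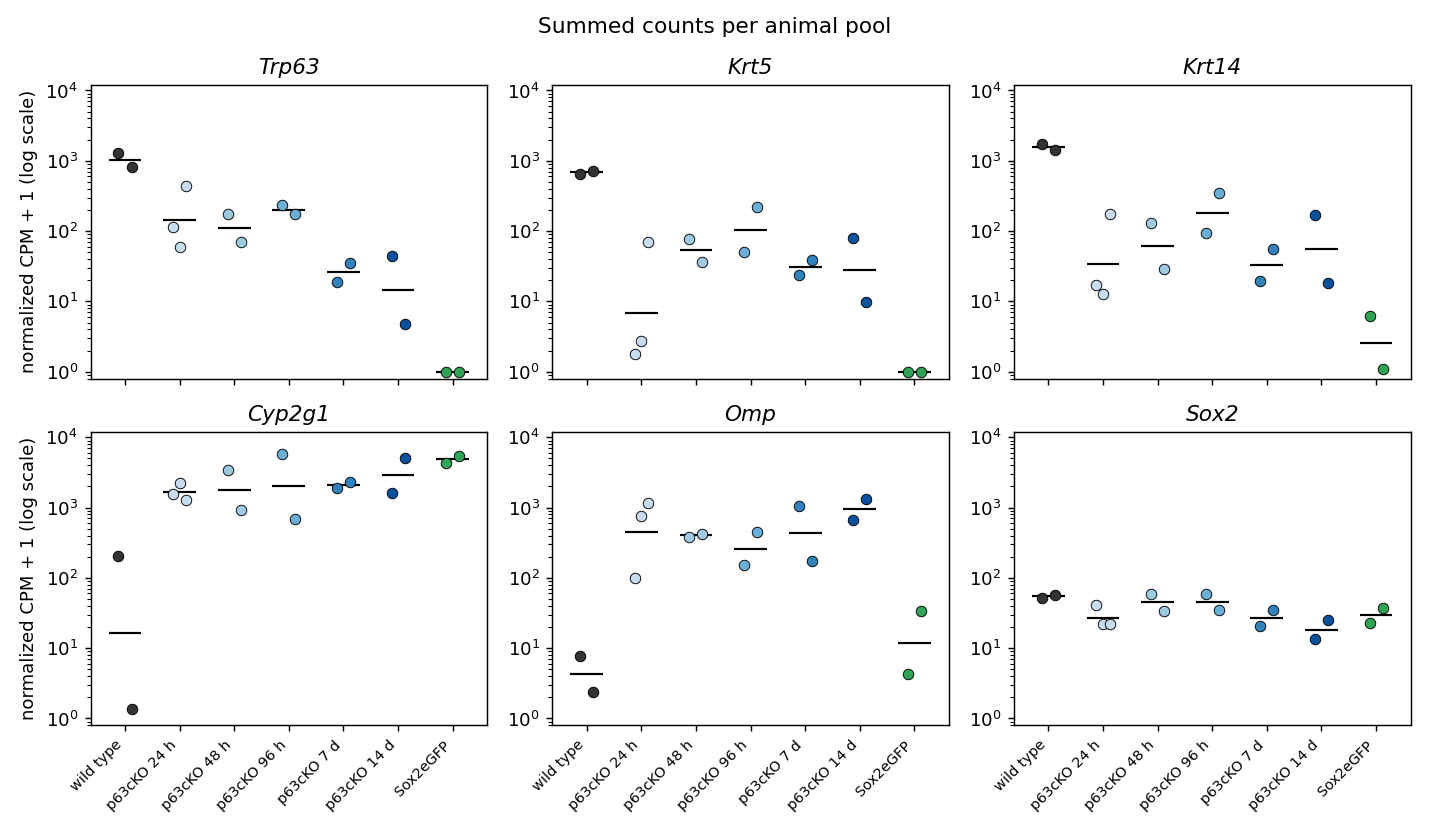
Normalized CPM + 1 (vertical log axis) of Trp63, Krt5, Krt14, Cyp2g1, Omp and Sox2 in each of the 15 pools by group (horizontal axis); points are pools and lines the mean of the logs. The wild type points of Trp63 lie at 1299 and 807 CPM, above all 11 p63cKO pools.

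At 24 h after tamoxifen, the pools of traced p63cKO cells held transcripts of the neuronal genes Dcx, Ncam1 and Rtp1. These were low or absent in wild type, which was collected at 72 h and 96 h. Few cells were neuron-like: of 87 kept at 24 h, the immature clusters 3 and 6 held 5 and 2, and the mature cluster 11 held 6. Whether these cells arose from marked basal cells within 24 h or entered the sort in another way was not tested. Dcx, a microtubule protein of young neurons (chromosome X, 143855842 to 143933311, minus strand, GRCm38), rose from 0.757 ± 0.452 to 404 ± 326 CPM (SD, n = 2 and 3 pools; log2 fold change 8.98 ± 1.24 SE, adjusted p = 0.0228). The neural adhesion molecule Ncam1 (chromosome 9, 49502136 to 49798925, minus strand) rose from 15.5 ± 14.4 to 528 ± 146 CPM (5.08 ± 0.80, adjusted p = 0.0436). Rtp1, which carries odorant receptors to the cell surface, had 0 counts in both wild type pools and 134 ± 97.3 CPM at 24 h, at least 3612-fold higher (adjusted p = 0.0152). Other genes that rose were the sulfotransferase Sult1c1 (6.57 ± 1.02), the tight junction gene Cldn9 (4.02 ± 0.59) and the cytochrome P450 gene Cyp2a5, from 74.1 ± 0.924 to 980 ± 31.4 CPM (3.73 ± 0.44, adjusted p = 0.0152). Reads of Cyp2a5 (chromosome 7, 26835305 to 26843548) may be shared with its near-identical copy Cyp2a4, so its level is uncertain. The other named risers were Arhgef28 (4.43), Spata13 (4.28) and the fatty acid transporter Slc27a2 (3.42). Genes that fell were the taurine transporter Slc6a6 (-1.95 ± 0.31, from 4086 ± 272 to 1054 ± 406 CPM) and the epithelial 14-3-3 gene Sfn (-2.52 ± 0.39). The netrin receptor Unc5c, named after its values were seen, had 0 counts at 24 h, at least 958-fold below its 74.8 ± 49.2 CPM in wild type (adjusted p = 0.0170).

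Of 19495 genes, 22 passed at 24 h (19 up, 3 down), all without overlap of the pools. Chance gives this for 20% of genes not picked by a test. Genes that pass with so few pools hardly ever overlap, so this is no added support, here or in the contrasts below. Of 7 immature neuron markers, 5 rose adjusted over the list alone and 2 over all genes (camera adjusted p = 4.63e-09; adjusted p = 0.115 with an estimated correlation). Of 9 mature neuron markers, 6 rose adjusted over the list alone and 1 over all genes (2.46e-07; adjusted p = 0.246 with an estimated correlation). Omp, which marks mature olfactory neurons, was at 675 ± 536 against 4.04 ± 3.73 CPM (7.36 ± 1.57, adjusted p = 0.120). The next 2 lists largely repeat these neuron markers and are no separate signals. All 9 mature ones are in the odorant transduction list, and all immature ones but Gng8 in the neurite growth list. The odorant transduction list rose (10 of 16 adjusted over the list alone, 2 over all genes, 2.55e-10; adjusted p = 0.181 with an estimated correlation). So did the neurite growth list (9 of 17 adjusted over the list alone, 2 over all genes, 3.35e-12; adjusted p = 0.115 with an estimated correlation). In the opposite direction, 5 of 7 horizontal basal markers fell adjusted over the list alone and 0 over all genes (0.000108; adjusted p = 0.100 with an estimated correlation), with Krt5 at 23.7 ± 38.9 against 689 ± 45.7 CPM (adjusted p = 0.284). Of 11 hemidesmosome and basement membrane genes, which anchor basal cells, 6 fell adjusted over the list alone and 0 over all genes (2.89e-05; adjusted p = 0.100 with an estimated correlation), led by Dst (-3.21 ± 0.58, adjusted p = 0.0665). Of 6 leukocyte markers, 2 fell adjusted over the list alone and 0 over all genes (0.0400; adjusted p = 0.441 with an estimated correlation), and the wild type level of the macrophage gene C1qb was 198 ± 280 CPM. Of 6 sustentacular markers 1, Cyp2a5, rose both adjusted over the list alone and over all genes (0.0142; adjusted p = 0.344 with an estimated correlation), and Cyp2g1 was at 1685 ± 466 against 102 ± 144 CPM (adjusted p = 0.327). DESeq2 called 1824 genes and limma on mean CPM 140, against 0 when only the compared groups were fitted, 0 with the stricter cell filter and 3 without the cells of cluster 12. Cluster 12 held 0 cells at 24 h and 1 in wild type, so this drop cannot come from 24 h cells of that cluster. The stricter filter left only 1 and 2 cells in 24 h replicates 1 and 2, and 3 in wild type replicate 2. The count was 42, 11 and 95 without 24 h replicates 1, 2 and 3, and 41 and 0 without wild type replicates 1 and 2. No sequencing run holds both groups, so run and genotype cannot be told apart. The sums of this and the later times also cannot tell a change within cells from a change in which cells were caught.

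At 48 h, the neuronal genes Ncam1 and Map1b stood above wild type and the desmosomal cadherin Dsc3 below it. Ncam1 rose to 563 ± 137 CPM (5.17 ± 0.82, adjusted p = 0.0483), and so did the neuronal microtubule gene Map1b (2.01 ± 0.30, adjusted p = 0.0376). Cldn9 (4.12 ± 0.61) and Cyp2a5 (3.47 ± 0.45, 821 ± 321 CPM) rose as well. Dsc3 fell from 683 ± 138 to 75.5 ± 2.24 CPM (-3.18 ± 0.44, adjusted p = 0.0282), the lysosomal protease gene Ctsl from 1265 ± 72.6 to 203 ± 1.02 CPM (-2.64 ± 0.40), and Slc6a6 to 743 ± 57.7 CPM (-2.46 ± 0.36, adjusted p = 0.0376; chromosome 6, 91684053 to 91759066, plus strand). In all, 16 genes passed (13 up, 3 down), none with overlapping pools, which chance gives for 33.3% of genes not picked by a test. Of the 7 horizontal basal markers, 5 fell adjusted over the list alone and 0 over all genes (camera adjusted p = 2.50e-06; adjusted p = 0.0362 with an estimated correlation). Of the 11 hemidesmosome genes 5 fell adjusted over the list alone and 0 over all genes (2.18e-07; adjusted p = 0.0362 with an estimated correlation). Krt14 was at 79.1 ± 72.5 against 1577 ± 188 CPM (-4.32 ± 1.79, adjusted p = 0.484). Of 9 desmosome genes, 3 fell adjusted over the list alone and 1 over all genes (0.00101; adjusted p = 0.0556 with an estimated correlation). Immature neuron markers (5 of 7 up adjusted over the list alone, 2 over all genes; 6.73e-08; adjusted p = 0.105 with an estimated correlation) and mature ones (6 of 9, 1 over all genes; 2.63e-06; adjusted p = 0.264 with an estimated correlation) rose. Of 16 immediate early genes, 6 fell adjusted over the list alone and 0 over all genes (4.62e-05; adjusted p = 0.316 with an estimated correlation), among them Jun (-1.16 ± 0.33) and Fos (-1.10 ± 0.35). DESeq2 called 1115 genes and limma on mean CPM 75, against 0 when only the compared groups were fitted, 0 with the stricter cell filter and 1 without cluster 12. The count was 6 and 5 without 48 h replicates 1 and 2, and 35 and 0 without wild type replicates 1 and 2. No run holds both groups.

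At 96 h, 6 genes were higher than in wild type and 0 lower. Cyp2a5 was the only one in the naming rule (3.87 ± 0.46, 1079 ± 585 CPM, adjusted p = 0.0223), and Rtp1, at 99.0 ± 3.40 CPM against 0 counts, was at least 2279-fold higher. All 6 were without overlap of the pools (chance share 33.3% of genes not picked by a test), and 1485 genes had an unadjusted p under 0.05. Of 9 mature neuron markers, 6 rose adjusted over the list alone and 1 over all genes (camera adjusted p = 9.52e-08; adjusted p = 0.167 with an estimated correlation). Of 7 immature ones 5 rose adjusted over the list alone and 0 over all genes (1.82e-07; adjusted p = 0.152 with an estimated correlation). The 6 globose basal markers passed as a list (0.00576; adjusted p = 0.293 with an estimated correlation) with 0 members passing adjusted over the list alone. Likewise the 7 horizontal basal markers passed as lower (0.00108; adjusted p = 0.152 with an estimated correlation) with 0 members adjusted over the list alone, and Krt14 was at 218 ± 177 CPM. Within the 2 runs that hold both groups, 1 pool against 1 with the spread taken from other groups, edgeR called 15 genes. The count was 13 without 96 h replicate 1, 26 without wild type replicate 1 and 0 without wild type replicate 2. It was 0 when only the compared groups were fitted, 0 with the stricter cell filter, 1 without cluster 12, 816 with DESeq2 and 16 with limma on mean CPM.

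By 7 d, traced p63cKO cells differed from wild type in 63 genes. Among the 43 that rose were the sodium channel gene Scn9a (7.54 ± 1.26, adjusted p = 0.0317), Ncam1 (5.79 ± 0.84, 867 ± 339 CPM), the olfactory neuron transcription factor Ebf2 (4.47 ± 0.78) and the presenilin gene Psen2 (4.34 ± 0.65). Sult1c1 (6.70), Ell3 (5.54), Cldn9 (5.24 ± 0.64, 557 ± 145 CPM, adjusted p = 0.00805), Arhgef28 (4.25), Cyp2a5 (3.94) and Ppp1r16b (3.87) completed the named risers. Among the 20 that fell was Dst, which links keratin filaments to hemidesmosomes (-4.39 ± 0.71, from 2271 ± 29.5 to 109 ± 16.3 CPM, adjusted p = 0.0297). Others were the 5-alpha-reductase Srd5a2 (-4.17), the Kit ligand Kitl (-3.54), Slc6a6 (-3.27 ± 0.37, adjusted p = 0.00795), Dsc3 (-3.11) and Ctsl (-2.94). Nfe2l3 (-4.32), the sodium pump subunit Atp1b3 (-3.50), the secretoglobin Scgb1c1 (-3.36) and the amino acid transporter Slc38a2 (-2.93) also fell. All 63 were without overlap, which chance gives for 33.3% of genes not picked by a test. All 7 horizontal basal markers fell adjusted over the list alone and 1, Aqp3, over all genes (camera adjusted p = 5.41e-07; adjusted p = 0.0311 with an estimated correlation). Of the 11 hemidesmosome genes, 5 fell adjusted over the list alone and 1 over all genes (1.42e-06; adjusted p = 0.0311 with an estimated correlation). All 7 immature neuron markers rose adjusted over the list alone and 2 over all genes (1.05e-07; adjusted p = 0.102 with an estimated correlation). Of 9 mature ones 6 did so, with 1 over all genes (2.60e-06; adjusted p = 0.216 with an estimated correlation). DESeq2 called 1802 genes and limma on mean CPM 323, against 0 when only the compared groups were fitted, 0 with the stricter cell filter, 18 with the share of medium chips as a covariate and 9 without cluster 12. The count was 10 and 22 without 7 d replicates 1 and 2 and 0 without wild type replicate 2. No run holds both groups.

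At 14 d the traced cells were rich in transcripts of olfactory neurons. Omp rose from 4.04 ± 3.73 to 999 ± 483 CPM (7.92 ± 1.63, adjusted p = 0.0469), Dcx to 486 ± 28.4 CPM (9.25 ± 1.26, adjusted p = 0.00677), Ncam1 to 1770 ± 49.0 CPM (6.82 ± 0.88, adjusted p = 0.00597) and Scn9a to 590 ± 19.0 CPM (8.28 ± 1.30). Rtp1 was at 423 ± 237 CPM, at least 11110-fold above wild type. Dystrobrevin Dtna (7.39), the proteoglycan Spock1 (6.10), the proton pump gene Atp6v0e2 (5.98), Ell3 (5.79), Sult1c1 (5.72) and the synaptic scaffold Homer2 (5.44) were the other named risers. The falls included the semaphorin Sema5a (-7.41 ± 1.17, from 826 ± 30.9 to 4.83 ± 3.52 CPM, adjusted p = 0.0125), the glutathione transferase Gsto1 (-6.46), the chemokine Cx3cl1 (-6.31), Gas1, a growth arrest gene (-5.60 ± 0.67, adjusted p = 0.00483), and Fras1, a basement membrane protein (-5.47). Arhgef5 (-5.60), Scgb1c1 (-5.17), the peptide transporter Slc15a2 (-5.08), Luzp1 (-5.07) and Srd5a2 (-5.06) fell as well. Krt5, at 44.1 ± 50.1 CPM, did not pass (-3.96 ± 1.81, adjusted p = 0.302).

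In total 190 genes passed at 14 d (98 up, 92 down), all without overlap (chance share 33.3% of genes not picked by a test). As at 24 h, the odorant transduction and neurite growth lists below repeat the mature neuron markers and most immature ones. Of the 9 mature neuron markers, 7 rose adjusted over the list alone and 3 over all genes (camera adjusted p = 2.35e-07; adjusted p = 0.176 with an estimated correlation), and all 7 immature ones rose adjusted over the list alone, 2 over all genes (4.57e-08; adjusted p = 0.106 with an estimated correlation). Odorant transduction genes (11 of 16 up adjusted over the list alone, 5 over all genes; 1.87e-09; adjusted p = 0.162 with an estimated correlation) and neurite growth genes (13 of 17, 3 over all genes; 8.36e-11; adjusted p = 0.106 with an estimated correlation) rose. Horizontal basal markers (6 of 7 down adjusted over the list alone, 1 over all genes; 1.86e-06; adjusted p = 0.0236 with an estimated correlation) and hemidesmosome genes (8 of 11, 2 over all genes; 3.17e-07; adjusted p = 0.0236 with an estimated correlation) fell. Of 9 desmosome genes, 7 fell and 1 rose adjusted over the list alone, and 3 fell over all genes (8.26e-05; adjusted p = 0.0236 with an estimated correlation): Dsc3 (-2.89), Dsp (-3.04) and Dsg2 (-2.58). Of 20 Wnt pathway genes, 2 fell both adjusted over the list alone and over all genes (0.00249; adjusted p = 0.0507 with an estimated correlation), the secreted Wnt antagonist Sfrp1 (-2.76 ± 0.50) and the transcription factor Tcf7l2 (-1.83 ± 0.39). Of 16 immediate early genes, 11 fell adjusted over the list alone and 1, Fos, over all genes (1.99e-05; adjusted p = 0.305 with an estimated correlation). DESeq2 called 2508 genes and limma on mean CPM 918, against 18 when only the compared groups were fitted, 99 with the share of male animals as a covariate and 0 with the stricter cell filter. The count was 41 and 51 without 14 d replicates 1 and 2, and 116 and 44 without wild type replicates 1 and 2. No run holds both groups.

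Between successive times, and over the 5 p63cKO times together, edgeR called 0 genes. The mitosis list passed as lower at 24 h than at 48 h with the preset correlation only: of 19 genes, 2 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 2.49e-08; adjusted p = 0.648 with an estimated correlation). Cenpf was at 172 ± 105 CPM at 48 h against 23.3 ± 25.2 at 24 h. Aurkb was at 39.1 ± 13.9 CPM at 48 h against 0.233 ± 0.257 at 24 h. Wound-type keratinocyte genes (8 measured) were higher at 96 h than at 48 h as a list (0.00110; adjusted p = 0.289 with an estimated correlation) with 0 members passing adjusted over the list alone, and lower at 7 d than at 96 h (0.00120; adjusted p = 0.120 with an estimated correlation), where 1 member fell adjusted over the list alone. That member, Krtdap, was at 23.6 ± 22.2 CPM at 96 h and 0 counts at 7 d. Of the 17 wound-keratinocyte-like cells, 14 were in 96 h replicate 2 and 0 in 96 h replicate 1, so 1 pool holds most of these cells. From 96 h to 7 d the 12 interferon response genes (0.00120; adjusted p = 0.120 with an estimated correlation) and the 7 horizontal basal markers (0.00120; adjusted p = 0.120 with an estimated correlation) passed as lower, each with 0 members adjusted over the list alone. From 7 d to 14 d, 19 mitosis genes were lower as a list (0.000649; adjusted p = 0.708 with an estimated correlation), and 9 mature neuron markers higher (0.0350; adjusted p = 0.708 with an estimated correlation), again with 0 members adjusted over the list alone. At an unadjusted p under 0.05 there were 1456 genes between 24 h and 48 h, 317 higher and 199 lower from 48 h to 96 h, 832 from there to 7 d, 796 to 14 d and 1631 over all times. Chance alone gives such a p for a fraction of about 0.05 of the 19495 genes tested. The counts from 48 h to 96 h, to 7 d and to 14 d lie below that number. In the same order, DESeq2 called 655, 149, 268, 245 and 826, and limma on mean CPM 0, 0, 0, 0 and 19. Leaving out 24 h replicate 1 gave 1 gene and leaving out 24 h replicate 3 gave 6 between 24 h and 48 h. Within runs that hold both times edgeR called 0 genes in each of 4 comparisons of 1 pool with 1 or 2 (spread mostly from other groups), with 176 to 1513 at an unadjusted p under 0.05.

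Summed over pools, Sox2eGFP cells had higher levels of tuft-type microvillous genes than wild type cells. Horizontal basal genes were lower after a sort against ICAM. Horizontal-basal-like cells made up 0.0% of the Sox2eGFP cells and 90.7% of wild type cells (group means), so the falls of genes these cells carry cannot be told apart from the sort. Krt5 had 0 counts against 689 ± 45.7 CPM in wild type, at least 15430-fold lower (adjusted p = 0.0328), and the keratin Krt17 fell from 2947 ± 499 to 5.66 ± 0.305 CPM (-9.02 ± 1.14, adjusted p = 0.00479). Sema5a (-9.72), Gsto1 (-8.15), the matrix gene Efemp1 (-7.17), Srd5a2 (-6.71), the caveolar gene Ptrf (-6.47), the adhesion gene Nrcam (-6.38), the hyaluronidase Hyal1 (-6.23) and Rbms3 (-5.99) fell. F3, lower too (-6.12), was itself a gate of the sort. Risers were Sult1c1 (7.53 ± 1.08, 2542 ± 190 CPM) and Tfcp2l1, a factor of ion-transporting epithelia (6.50 ± 1.05, 497 ± 95.8 CPM). With them rose the copper pump Atp7b (5.02), Ell3 (4.97), Cldn9 (4.62), Ppp1r16b (4.43), Slc27a2 (4.41 ± 0.55, adjusted p = 0.00479), Nelfcd (4.25), Ncam1 (4.17) and Pik3r3 (4.11). In all 202 genes passed (59 up, 143 down), all without overlap (chance share 33.3% of genes not picked by a test). Of 7 tuft-type microvillous markers, 5 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 1.97e-07; adjusted p = 0.00483 with an estimated correlation), such as Sh2d7 at 132 ± 11.8 against 0.350 ± 0.495 CPM. No cluster was tuft-type by name. Sh2d7 was detected in 11.5% of the cells of cluster 5, which held 23 Sox2eGFP cells, and in 2.8% of cluster 10. Few cells may therefore carry these sums. Of 6 ionocyte-type markers 4 rose adjusted over the list alone and 0 over all genes (0.0108; adjusted p = 0.253 with an estimated correlation). Of 6 globose basal markers 3 did so and 0 over all genes (0.00156; adjusted p = 0.223 with an estimated correlation). Of 11 hemidesmosome genes, 8 fell adjusted over the list alone and 3 over all genes (5.79e-10; adjusted p = 0.00483 with an estimated correlation). Desmosome genes fell too (5 of 9 adjusted over the list alone, 3 over all genes, 5.58e-05; adjusted p = 0.0151 with an estimated correlation). Of 16 immediate early genes, 15 fell adjusted over the list alone and 7 over all genes (7.19e-12; adjusted p = 0.123 with an estimated correlation), among them Jun (-2.16 ± 0.34), Junb (-3.61 ± 0.60) and Fos (-2.14 ± 0.36). DESeq2 called 1936 genes and limma on mean CPM 611, against 0 with the stricter cell filter and 110 with the share of male animals as a covariate. The count was 52 and 26 without Sox2eGFP replicates 1 and 2, and 59 without wild type replicate 2. Sort, sequencing run and group coincide and cannot be told apart.

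Against p63cKO 14 d, the summed Sox2eGFP cells had more transcripts of tuft-type microvillous markers, though few cells may carry them. In cluster 5 the marker Il25 was detected in 8.2% of cells. Lists of mitosis and mature neuron genes passed only with the preset correlation. Of 7 tuft-type markers, 3 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 4.18e-09; adjusted p = 0.00670 with an estimated correlation), with the tuft cytokine Il25 at 138 ± 17.5 CPM against 0 counts, at least 3380-fold higher. Of 19 mitosis genes, 2 rose adjusted over the list alone and 0 over all genes (6.50e-10; adjusted p = 0.358 with an estimated correlation), Cdc20 at 25.2 ± 12.9 against 0.0303 ± 0.0123 CPM and Cenpf at 252 ± 9.50 against 26.0 ± 16.6 CPM. Of 9 mature neuron markers, 6 fell adjusted over the list alone and 0 over all genes (4.18e-09; adjusted p = 0.295 with an estimated correlation), and Omp was at 17.9 ± 20.7 against 999 ± 483 CPM. Single genes that passed were 2, both lower: Sfn (6.30 ± 0.746 against 114 ± 15.5 CPM; -4.17 ± 0.49, adjusted p = 0.0421) and the estrogen receptor Esr1, named after its values were seen, with 0 counts against 12.6 ± 1.11 CPM, at least 342-fold lower (adjusted p = 0.0421). Both were without overlap (chance share 33.3% of genes not picked by a test). At an unadjusted p under 0.05 there were 1559 genes, and DESeq2 called 783 and limma on mean CPM 14. The count was 1 without Sox2eGFP replicate 1 and 0 without Sox2eGFP replicate 2, 14 d replicate 1 or 14 d replicate 2, with either covariate, with the stricter cell filter, or with the compared groups alone.

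Within horizontal-basal-like cells alone, each p63cKO time is a single pool, of 14 cells at 24 h, 13 at 48 h and 17 at 96 h, so levels are given as values of these pools. Trp63 was at 1298 CPM at 24 h (log2 fold change 0.42), 356 at 48 h (-1.45) and 883 at 96 h (-0.14), against a mean of 974 in the wild type pools. Krt14, one of the markers that named the class, was at 586 CPM at 24 h, 210 at 48 h and 906 at 96 h, against 1440 in wild type. Omp was at 224 CPM at 24 h, 47.6 at 48 h and 0 at 96 h, against 3.82 in wild type. Over single cells the mean log2(CPM + 1) of Trp63 was 7.24 ± 3.65 (SD over 53 p63cKO cells) and 9.04 ± 2.30 (93 wild type cells). Of 14847 genes, edgeR called 457 at 24 h, 79 at 48 h and 390 at 96 h, but the only spread in this fit is that between the wild type pools (1 residual degree of freedom), and limma on mean CPM called 0, 0 and 0 against 2322, 989 and 2158 by DESeq2. In the fitted pools cluster 7 held 36 of the 93 wild type cells, 1 of 14 at 24 h, 10 of 13 at 48 h and 1 of 17 at 96 h.

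The kinds of cell caught differed between the groups. Changes of pool sums against wild type therefore cannot be told apart from changes in which cells were summed. Horizontal-basal-like cells were 90.7 ± 3.1% of wild type cells (SD over 2 pools; 93 of 103), but 11.1 ± 19.2% at 24 h (n = 3), 15.5 ± 16.4% at 48 h, 12.3 ± 4.1% at 96 h, 1.8 ± 0.2% at 7 d and 2.0 ± 2.8% at 14 d. At 24 h all 14 such cells came from replicate 3. None was among the 142 Sox2eGFP cells (Wilson 95% upper bound 2.6%), a group gated against ICAM. Cluster 1 held 41.6 ± 32.1% of cells at 24 h (4.8 to 63.6%), 22.1 ± 7.6% at 48 h, 39.0 ± 11.1% at 96 h, 11.6 ± 2.3% at 7 d and 3.0 ± 4.2% at 14 d, against 0.8 ± 1.1% in wild type. Cluster 4 held 28.8 ± 4.0% at 7 d and 18.2 ± 9.0% at 14 d, and cluster 9 held 23.8 ± 11.2% of Sox2eGFP cells. Wound-keratinocyte-like cluster 15 came largely from 1 pool, with 14 of its 17 cells in 96 h replicate 2. Cells of the neuronal lineage (globose-basal-like to mature-neuron-like) were 0.8 ± 1.1% of wild type cells, 15.3 ± 7.6% at 24 h, 34.2 ± 7.1% at 48 h, 20.3 ± 6.6% at 96 h, 39.6 ± 9.0% at 7 d and 57.8 ± 18.2% at 14 d. They made up 40.4 ± 1.9% of Sox2eGFP cells, which also held 17.8 ± 4.0% microvillous-like cells.

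**Figure D3:**
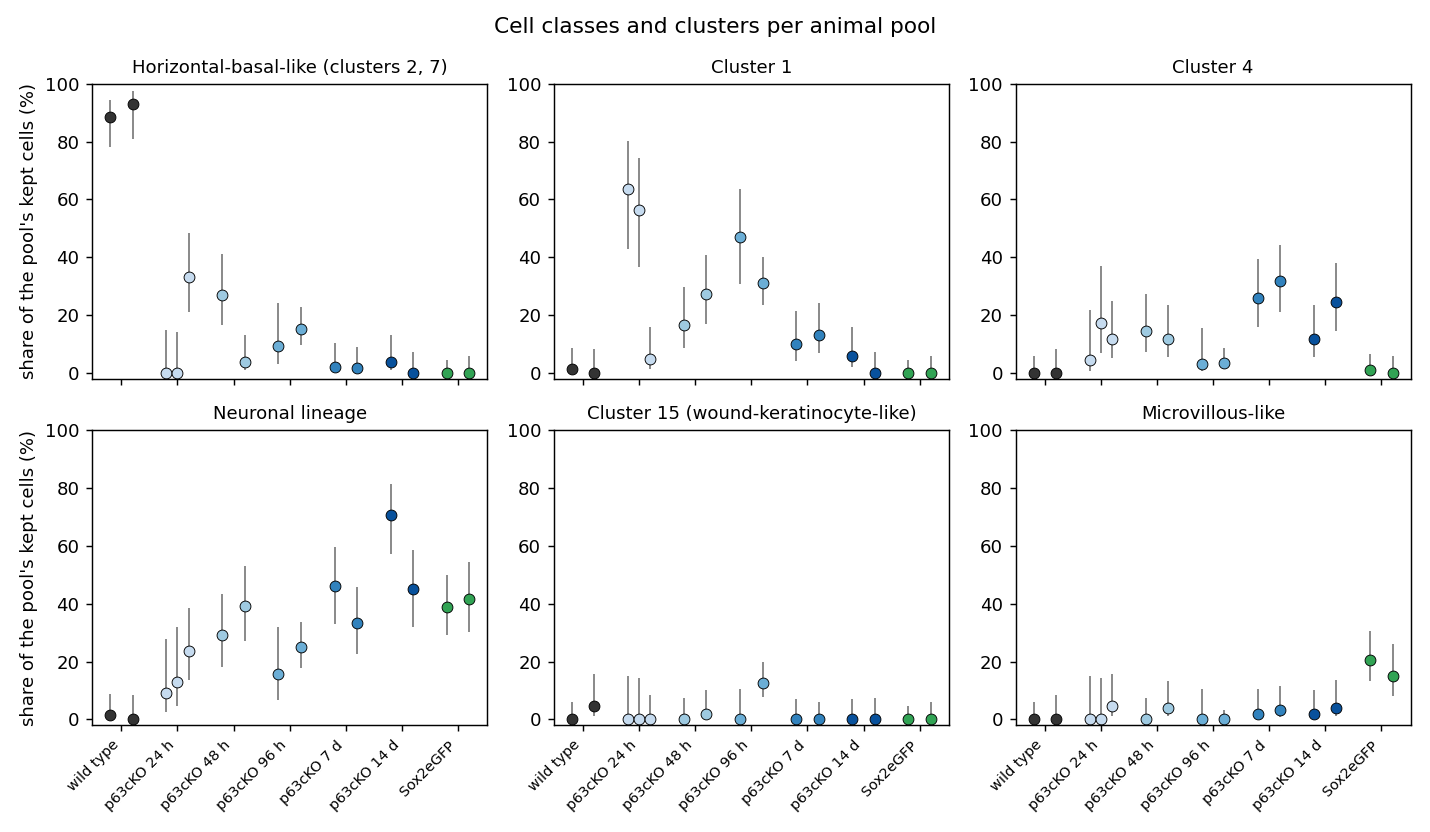
Share of kept cells in percent (vertical axis) per pool and group (horizontal axis) for 6 classes or clusters; points are pools, bars their 95% Wilson intervals (counting error only). Neuronal lineage cells average 0.8% in wild type and 57.8% at p63cKO 14 d.

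Over the 11 p63cKO pools, the share of neuronal lineage cells rose with time after tamoxifen (Spearman's rho = 0.81, permutation p = 0.00433, adjusted over 4 classes p = 0.0173; Pearson's r = 0.81, permutation p = 0.00225). Without the 2 pools farthest from the median time r was 0.61. The horizontal-basal-like share (rho = -0.15, permutation p = 0.667, adjusted p = 0.667; r = -0.40, permutation p = 0.211) and the microvillous-like share (rho = 0.26, permutation p = 0.441, adjusted p = 0.588; r = 0.33, permutation p = 0.331) showed no trend that passed, nor did the summed share of clusters 4 and 9 (rho = 0.34, permutation p = 0.307, adjusted p = 0.588; r = 0.39, permutation p = 0.241, and 0.63 without the 2 farthest pools). By cluster number none of 15 passed, with the immature-neuron-like cluster 3 at rho = 0.72 (permutation p = 0.0154, adjusted p = 0.224). The neuronal trend missed the threshold without 24 h replicate 1 (rho = 0.76, adjusted p = 0.0602), 24 h replicate 2 (0.76, 0.0602) or 14 d replicate 1 (0.76, 0.0624), and at clustering resolution 0.5 or with 1000 variable genes (0.72, adjusted p = 0.0609 in both). No sequencing run holds 6 pools, so the trend was not computed within runs, and the 7 d and 14 d pools share no run with the earlier times. With the stricter cell filter the neuronal rho was -0.09 (adjusted p = 0.991). That filter left only 1 and 2 cells in 24 h replicates 1 and 2 and 6 in each 96 h pool, so shares there are rough.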

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

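Of the tests below, those of read mode and of 2 cells in 1 chamber were written before their values were seen; all others were chosen only after the result was seen.

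Spike-in reads were found in libraries whose labels give no spike-in dilution: 1238123 counts in p63cKO 24 h replicate 1 (19.9% of its gene counts), 1490985 in replicate 2 (16.8%), 160 in replicate 3 and 65 in p63cKO 48 h replicate 2. The CreER transgene had 508065 counts in the 13 pools of traced cells and 0 in the Sox2eGFP pools, and the eGFP reporter row had 68349 counts over all pools. Scaled to gene counts over all libraries without TMM factors, the eGFP row was at 30.6 and 37.5 CPM in the Sox2eGFP pools. Group means were 119 to 272 in traced cells. Those cells carry a yellow fluorescent reporter instead, and whether its reads enter the eGFP row was not tested. These levels may thus come from different reporters and are no check of the sort. Sox2 itself was at 29.2 ± 10.6 in Sox2eGFP cells against 54.2 ± 3.83 CPM in wild type (edgeR adjusted p = 0.612).

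The 190 genes that differ between p63cKO 14 d and wild type come from pools that also differ in read mode and run. Going from paired to single reads moved these genes in the direction of p63cKO 14 d by a median log2 of 0.0 in wild type replicate 2 (quartiles -0.39 to 0.35) and 0.65 in p63cKO 96 h replicate 1 (-0.29 to 1.67), or 0.34 with the moves of each gene averaged over both. The called median was 4.03, above both upper quartiles, which argues against read mode as the whole cause. With the share of medium chips as a covariate their median log2 change was 4.1. Medium chips gave 65 of 65 and 0 of 42 cells in the wild type pools, and 0 of 54 and 49 of 49 at 14 d. Chip size was thus balanced between the groups, so this covariate could hardly move the change. The groups share 0 sequencing runs, so an effect of the run stays open.

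Cluster 12 carries mature neuron and sustentacular markers together. Its cells detected a median of 1.39 times as many genes as the cells of clusters 4, 9 and 11 of their pools (bootstrap 1.34 to 1.48), which fits 2 cells captured in 1 chamber. The sustentacular markers lay a mean log2 of 7.72 above those of mature-neuron-like cells of the same pools (8.61 against 0.89). The clustering had split these cells on the same expression values, so the gap cannot decide on free RNA. Of its 25 cells, 11 were from p63cKO 14 d, all in replicate 2, and 3 were from Sox2eGFP. Medium chips gave 18 of the 25 cells, and 14 d replicate 2 was on medium chips alone. No value here tells a cell between states from a pair of cells.

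At p63cKO 24 h all 14 horizontal-basal-like cells came from replicate 3. Replicates 1 and 2 held 77.3% of the counts of the 7 basal markers expected at the level of replicate 3 (14558 of 18827), which meets the bound set for shallow depth as the cause, and without Aqp3, which other clusters carry as highly, 37.9% (2591 of 6831), which lies between the bounds; the second reading was added after the first was seen. A further test, added last and with the shares already known, argues against depth as the whole cause: 3 other p63cKO pools with medians no higher than that of replicate 2 were 17.2% horizontal-basal-like (33 of 192, Wilson 95% interval 12.5 to 23.2%), and Krt5 was at 0.764 and 1.72 CPM in replicates 1 and 2 against 68.6 in replicate 3. Other p63cKO cells of the run of replicates 1 and 2 were 18.8% horizontal-basal-like (of 160), which argues against the run. These 160 cells are among the 192 above, so the 2 readings are not independent. The 3 pools of the 192 cells had shares of 9.4, 15.2 and 27.1%, a spread that the interval leaves out. Only 1 pool of this time came from 3 animals, so an effect of the animals stays open, as does a part played by depth. Replicates 1 and 2 had more bases between genes (medians 21.9 and 20.1%) than replicate 3 (15.1%). Yet wild type replicate 2, at 24.4%, held 39 horizontal-basal-like cells of 42. Whether RNA quality played a part was not tested.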

How the results depend on the processing

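The single-read fit, the fit without cluster 12, the trends by cluster number, the trend with clusters 5 and 12, and the horizontal basal list without Icam1 were tests chosen only after the result was seen.

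The fall of Trp63 kept its direction under every alternative, and counts of called genes depended on the processing. Keeping every library gave 19, 17, 6, 62 and 189 genes against wild type in time order and 203 for Sox2eGFP. Most changes are out of reach of these designs: on simulated counts 23% and 19% of 16-fold changes were recovered in the 24 h and 14 d designs, and 1% and 0% of 4-fold ones. No paired analysis was possible because the labels give no numbers shared between groups, and the replicate numbers here only name pools. The cause was not tested for any shift below unless stated. Within horizontal-basal-like cells, the chip covariate and the fits without a wild type pool were not run, as no residual degrees of freedom were left.

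Counts against wild type are in the order 24 h, 48 h, 96 h, 7 d and 14 d (22, 16, 6, 63 and 190 in the report). With every gene of at least 1 count they were 123, 71, 50, 198 and 419. With DESeq2 they were 1824, 1115, 816, 1802 and 2508, and with limma on mean CPM 140, 75, 16, 323 and 918. With the compared groups alone they were 0, 0, 0, 0 and 18, where fewer pools inform the dispersion. The stricter cell filter, with 333 cells, gave 0, 0, 0, 0 and 0. It left only 1 and 2 cells in 24 h replicates 1 and 2, 3 in wild type replicate 2 and 6 in each 96 h pool. Single reads alone, which leave 12 cells of 1 wild type pool, gave 150, 118, 94 and 179 for 24 h to 7 d. Without cluster 12 they were 3, 1, 1, 9 and 126. The medium chip covariate gave 11 at 24 h, 10 at 48 h and 18 at 7 d, and the male share 9, 8, 39 and 99 at 24 h, 48 h, 7 d and 14 d. RSEM gave 45 at 24 h and 12 at 96 h, and kallisto 58, 35 and 12 for 24 h to 96 h. Leaving out 1 pool gave ranges of 0 to 95, 0 to 35, 0 to 26, 0 to 70 and 41 to 116. The single values were 42, 11 and 95 without 24 h replicates 1 to 3, 6 and 5 without 48 h replicates 1 and 2, 13 without 96 h replicate 1, 10 and 22 without 7 d replicates 1 and 2, and 41 and 51 without 14 d replicates 1 and 2. Without wild type replicate 1 they were 41, 35, 26 and, at 14 d, 116, and without wild type replicate 2 they were 0, 0, 0, 0 and 44.

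For Sox2eGFP against wild type (202) the counts were 384 with every gene, 110 with the male share, 0 with the stricter filter, 611 with limma, 1936 with DESeq2, 59 without wild type replicate 2, and 52 and 26 without Sox2eGFP replicates 1 and 2 (range 26 to 155). Against p63cKO 14 d (2) they were 1 with median-of-ratios factors, 40 with every gene, 8 with RSEM, 1 with kallisto, 14 with limma and 783 with DESeq2. They were 0 with the chip covariate, the male share, the stricter filter, single reads, the compared groups alone, and without 14 d replicate 1, 14 d replicate 2 or Sox2eGFP replicate 2, and 1 without Sox2eGFP replicate 1.

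Between successive times (0 each) DESeq2 gave 655, 149, 268 and 245, and RSEM 2 from 96 h to 7 d. From 24 h to 48 h every gene of at least 1 count gave 1, and the fits without 24 h replicates 1 and 3 gave 1 and 6. Over the 5 times (0) there were 66 with every gene, 2 with RSEM, 19 with limma and 826 with DESeq2.

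Within horizontal-basal-like cells (457, 79 and 390) the counts were 884, 260 and 832 with every gene, 0, 0 and 0 with limma, and 2322, 989 and 2158 with DESeq2. Median-of-ratios factors gave 7.0e+02 at 24 h (221 up, 480 down) and 152 at 48 h. RSEM gave 158 and resolution 0.5 gave 174 at 48 h, and resolution 2 gave 249 at 96 h. The horizontal basal list without Icam1 in Sox2eGFP cells is not given, as a sort against ICAM sets its outcome. Of 118 list tests, 12 held with the estimated correlation.

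Trp63 (-3.73) ranged from -4.26 to -3.34 with 1 pool left out. It missed the threshold at -3.74 with the chip covariate (adjusted p = 0.0586), -3.53 with the stricter filter (0.279), -3.00 with single reads (0.124) and -3.75 without cluster 12 (0.0574). It also missed it without wild type replicate 1 (-3.34) or 2 (-4.04), 48 h replicate 2 (-3.63), 96 h replicate 1 (-3.78) or 2 (-3.69), or 7 d replicate 1 (-3.65).

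The neuronal trend (rho 0.81) was 0.72 at resolution 0.5 and 0.72 with 1000 variable genes (adjusted p = 0.0609 in both), -0.09 with the stricter filter, 0.76 without 24 h replicate 1, 24 h replicate 2 or 14 d replicate 1, and 0.80 with clusters 5 and 12 counted in. The horizontal-basal-like trend (rho -0.15) turned to 0.02 with the stricter filter, 0.04 without 24 h replicate 3 and 0.01 without 14 d replicate 2. With 1 pool left out the ranges were 0.76 to 0.88 (neuronal), -0.41 to 0.04 (horizontal-basal-like), 0.20 to 0.50 (clusters 4 and 9 summed, 0.34 in the report) and 0.13 to 0.60 (microvillous-like).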

Other observations

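The relation of CreER to the keratins was a test chosen only after the result was seen.

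Between Sox2eGFP cells and p63cKO 14 d, lists of DNA replication and of immediate early genes passed with the preset correlation but not with an estimated one. The 18 DNA replication genes all had positive values and passed as a list (camera adjusted p = 0.000122; adjusted p = 0.358 with an estimated correlation), with 0 members adjusted over the list alone. Of 16 immediate early genes, 4 fell adjusted over the list alone and 0 over all genes (0.000705; adjusted p = 0.485 with an estimated correlation), led by Jun at 317 ± 9.81 against 866 ± 94.1 CPM. Against wild type, the 18 cholesterol synthesis genes passed as lower in Sox2eGFP cells (0.0172; adjusted p = 0.253 with an estimated correlation), with 0 members adjusted over the list alone. The 6 neuronal precursor markers passed as higher (0.000314; adjusted p = 0.0957 with an estimated correlation), with 1 member up adjusted over the list alone and 1 over all genes.

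The CreER transgene, which is driven by the Krt5 promoter, stood at 4087 ± 1900 in wild type, 1573 ± 76.9 at p63cKO 24 h, 1685 ± 290 at 48 h, 1917 ± 785 at 96 h, 761 and 649 in the pools at 7 d, and 435 ± 28.5 at 14 d (SD over pools), in CPM of gene counts over all libraries without TMM factors. Over the 13 traced pools no relation passed with Krt5 (Pearson's r = 0.42, permutation p = 0.151, adjusted p = 0.302; 0.73 without the 2 farthest pools) or Krt14 (r = 0.53, permutation p = 0.0614, adjusted p = 0.246; 0.10 without the 2 farthest pools). Over the 11 p63cKO pools r was -0.01 with Krt5 (permutation p = 0.983) and 0.10 with Krt14 (permutation p = 0.758).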
